A study of Homo sapiens with 36 samples.

How the data were processed

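Total RNA from HK-2 cells, an immortalized line of human renal proximal tubule epithelial cells, was hybridised as biotin-labelled cRNA to single-colour Affymetrix arrays (U133 Plus 2.0 design), 1 array per culture. The labels name 36 arrays in 12 groups of 3 biological replicates. Cells received a compound labelled Aa for 24 h or 48 h, or a compound labelled Ota for 24 h or 72 h, at a high or a low dose, and each compound and time had its own vehicle controls. The labels do not spell out the compound names or give the concentrations, so the doses are called high and low here and are not matched between compounds. Per the labels' protocols, cells were seeded 24 h before treatment and treated near confluence in a serum-free medium with hormone and growth factor supplements.

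The deposited values are log2 expression values per probe set made by the authors with GCRMA, per the submitters' processing notes. GCRMA subtracts a background estimated from probe sequence, normalizes the arrays to each other and summarises the probes of a set. The GCRMA version, and whether all 36 arrays were normalized together, are not given in the sources used here. No detection calls, scan dates or slide positions were among the values used, so array batches could not be tested. The deposited log2 values ran from 0.844 at the lowest minimum to 16.09 at the highest maximum, and array medians lay between 2.88 and 3.13. For arrays, their number limits the precision: each pair of groups compared sets 3 arrays against 3, and the interactions also rest on groups of 3.

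Of 54675 probe sets, 62 Affymetrix control sets were left out of all tests. In the platform annotation, 41091 of the rest had 1 gene symbol, 1801 had several and were not named, and 11721 had no symbol in the table used. Entrez identifiers of 41037 probe sets matched a RefSeq gene table (assembly GRCh38.p14), and 0 symbols needed an update. That table was used for names only, and no coordinates are given because the values name no genome build. Each of 19775 genes was represented by 1 probe set, the one with the highest mean over all arrays, with sets ending in _x_at taken only where a gene had no other; 10523 genes had more than 1 probe set. Of the 342 pairs of named gene and comparison, 152 had another probe set past the filter and 11 had another probe set called the other way; this is pointed out where the report names such a gene in that comparison.

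A gene was tested if its log2 value exceeded 4 on at least 3 arrays of the compound, which left 10972 genes for Aa and 11029 for Ota, 10649 of them in both, and 11405 over all arrays. Levels at or under 4 have no dependable order on this platform. Where all 3 arrays of the dimmer group were at or under 4, the fold is therefore given as a lower bound ("at least"), against the higher of 4 and the array's own value. Where only some arrays of a group were at or under 4, the fitted change still rests on those values. The change with all values at or under 4 set to 4 is therefore given beside it as the floored value where it moved the change by over 0.1 (log2). This was so for 58 pairs of named gene and comparison without a lower bound. Linear models with group means were fitted in limma 3.58.1 under R 4.3.3 (lmFit, eBayes) to the 18 arrays of a compound, which leaves 12 residual degrees of freedom, or to all 36 arrays for the comparison of compounds. Genes were called at an adjusted p under 0.05 (Benjamini-Hochberg within a comparison, two-sided). Log2 changes are given ± SE from limma and group levels as mean ± SD. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

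The 17 comparisons were each dose against its control (8), high against low dose (4), the change in the high dose effect with time (2, as interactions), the later against the earlier controls (2) and the high dose effect of Ota against that of Aa at 24 h (1, an interaction). Before the data were examined, 28 gene lists with 755 distinct genes were fixed, of which 675 had a probe set. Lists with at least 5 tested members were tested with camera in limma at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation. The distal nephron, fibroblast, endothelial and leukocyte marker lists had fewer tested members and were not tested as lists. Genes named in the text were chosen by a rule fixed at the same time. For each high dose comparison it took the 8 largest rises and the 8 largest falls among called genes whose treated arrays all lay beyond all control arrays, the 2 most changed called members of each list that was called or had at least 25% of its members called, and CDKN1A, MDM2, HMOX1, NQO1, DDIT3, HAVCR1 and MKI67. For the other comparisons it took the 3 largest changes each way. Loci and open reading frames without a gene name were passed over.

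Replicates had Pearson correlations over the tested genes between 0.950 and 0.994. Over the 630 pairs of arrays at most 15 of 54613 values were identical, so no array's values appear more than once. Replicate numbers are shared between groups in the labels. Deviations from the group means correlated above 0.1 for every number in the Aa comparisons (lowest 0.189), in Ota high dose against control (0.109) and low dose against control (0.312) at 24 h, and in the comparison of the compounds (0.104). In these the numbers were taken as pairing the cultures, and the fit with the replicate number as a block is given where it changed a call or moved a count by over 1.5 times. The block was set within a compound and time, so it did not pair controls of different times. In the Ota comparisons at 72 h, the Ota dose comparisons, the Ota controls over time and the 72 h part of the Ota time comparison, at least 1 number fell below 0.1.

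The scripts were tested on simulated arrays with 200 changed genes. For Aa high dose against control at 24 h, over 10972 genes, 32.8% of the genes changed by 0.5 on the log2 scale were recovered, 80.6% of those changed by 1 and 98.5% of those changed by 2. For Ota high dose against control at 24 h, over 11029 genes, these shares were 22.4%, 59.7% and 93.9%. For the compound comparison, over 11405 genes, they were 2.99%, 46.3% and 86.4%. Among the calls, 4.73%, 4.10% and 6.25% were genes that had not been changed. A simulated list of 30 genes raised by 0.5 was called in each of the 3 comparisons and 0 of 27 unchanged lists were. The noise was drawn independently for each gene, so the simulation says nothing on false list calls from correlated members. Far fewer genes were changed in it than were called with the high doses.

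The alternatives tried were quantile normalization, a shift of each array to the same median over the tested genes, no filter or a stricter filter (6), every probe set by itself, the mean of a gene's probe sets, only the arrays compared, all 36 arrays in 1 fit, eBayes with trend and robust settings, the replicate block, and leaving out each array. The 24 h Ota controls in place of the 72 h ones, values at or under 4 set to 4, and the replicate block together with an estimated correlation were added as alternatives after seeing the data.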

Results

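Gene expression was measured on 36 arrays of HK-2 cells, 3 biological replicates in each of 12 groups. The cells were treated with vehicle, a low dose or a high dose of Aa for 24 h or 48 h, or of Ota for 24 h or 72 h. Between 10055 and 10557 of the represented genes exceeded a log2 value of 4 on an array. A principal component analysis was run for each compound on its own 18 arrays. The first component held 65.3% of the variance for Aa and 54.8% for Ota, and the second 10.5% and 22.0%. In both analyses, control arrays lay at the low end of the first component and high dose arrays at its high end.

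**Figure D1:**
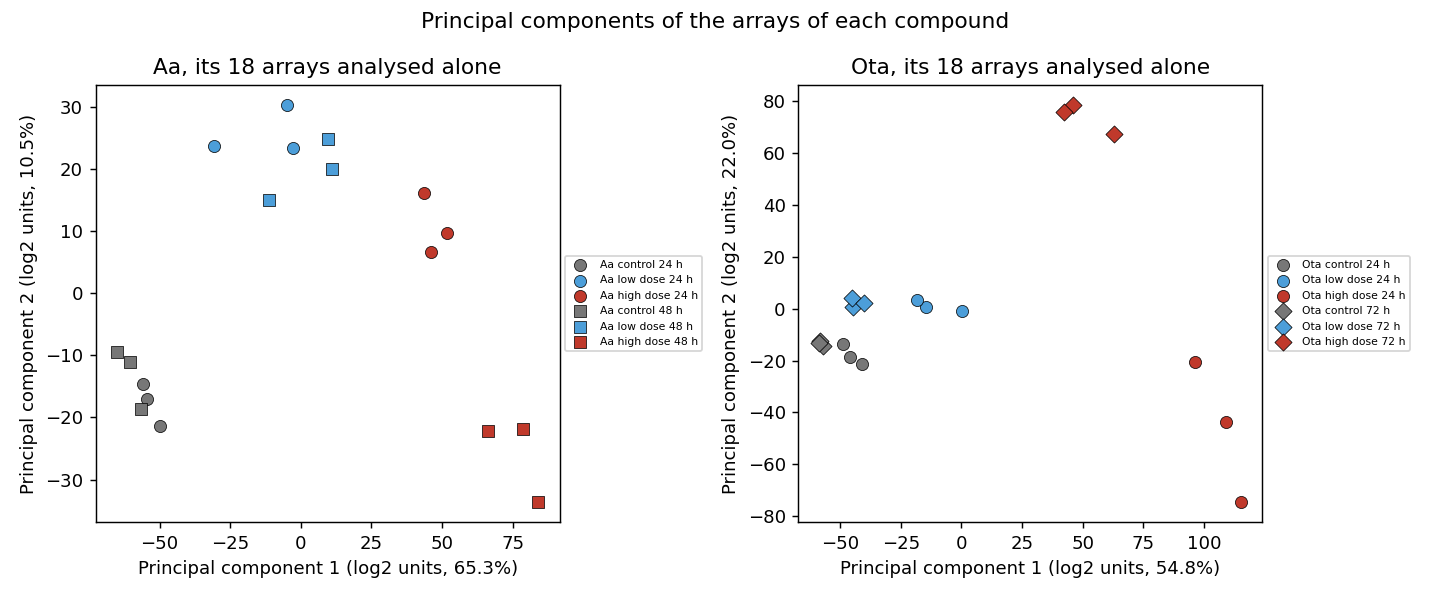
Scores of the arrays on principal components 1 and 2 (log2 units) from separate analyses of the 18 Aa arrays (left) and the 18 Ota arrays (right), with colour for dose (grey control, blue low, red high) and shape for time. Component 1, with 65.3% of the variance for Aa and 54.8% for Ota, separates the high dose arrays from the controls within each compound.

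The arrays of Ota high dose at 24 h stood apart. Their median log2 value over the tested genes was 7.64 ± 0.16 (SD, n = 3) against 8.28 ± 0.06 in the controls, and 10135 ± 81 of their genes exceeded 4 against 10453 ± 51. In Ota high dose at 72 h the median was 7.95 ± 0.05 against 8.28 ± 0.02. Their replicates at 24 h were also the least alike, with r from 0.950 to 0.981. The difference between the 3' and the 5' actin (ACTB) control sets, a sign of RNA quality, was 1.88 ± 0.37 in Ota high dose at 72 h against 1.29 ± 0.15 in its controls. It was 1.25 ± 0.30 in Aa high dose at 48 h against 0.86 ± 0.22.

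Markers of other cell types were read with the high doses, and the genes named here were chosen after their values were seen. In the controls CLDN16 of the distal nephron list had a mean of 9.37 with Aa, SCNN1A one of 9.66 with Ota, and the fibroblast gene DCN means of 11.2 and 9.83. ESAM, the endothelial marker that was tested, had control means of 4.94 and 6.20. PTPRC, of the leukocyte list, lay under 4 in the controls and was not tested. With Aa at 24 h, 1 of 3 distal nephron markers was called (CLDN16, -2.37), as were 2 of 4 fibroblast markers (DCN, -0.56; COL1A1, -0.65), 0 of 1 endothelial markers and the leukocyte marker FCER1G, whose arrays there all lay under 4. At 48 h CLDN16 (-2.89), S100A4 (-0.87) and FCER1G (2.18, floored 0.73) were called. With Ota at 24 h, AQP3 (1.05), LUM (0.62), S100A4 (1.05), ITGAM (2.61, floored 0.96) and FCER1G (4.03, floored 2.47) rose, and SCNN1A (-1.28) and COL1A1 (-2.07) fell. At 72 h AQP3 (2.04), LUM (1.58) and FCER1G (4.24, floored 2.77) rose, and SCNN1A (-1.93), CLDN16 (-2.88) and ESAM (-1.97) fell. These calls and directions held with quantile normalization and with shifted arrays. Shifted arrays also called SLC12A1, DCN and ESAM higher with Ota at 24 h and SLC12A1 and DCN at 72 h, and quantile normalization SLC12A1 at 24 h. With 1 array left out, calls were lost for DCN (adjusted p = 0.0887, 0.107 and 0.142 without control replicate 1 or 2 or high dose replicate 3) and COL1A1 (0.146, 0.0787, 0.0529 and 0.192 without control replicate 1 or 2 or high dose replicate 2 or 3) with Aa at 24 h. S100A4 with Aa at 48 h lost its call without control replicate 2 (0.0980) or high dose replicate 3 (0.0751), and LUM with Ota at 24 h without control replicate 2 (0.148) or high dose replicate 1 (0.124). ESAM with Aa at 24 h was called without control replicate 1 (0.0361) or 2 (0.04797), SLC12A1 with Ota at 24 h without high dose replicate 3 (0.0110) and DCN with Ota at 72 h without high dose replicate 3 (0.00885).

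The first question was what the high dose of Aa did within 24 h. Where setting values at or under 4 to 4 moved a log2 change or a list median by over 0.1 without a lower bound being given, the floored value follows it, an alternative chosen after seeing the data. Genes nearly silent in the controls came up to clear levels: AOC3 (probe set 204894_s_at), a membrane amine oxidase, reached 9.19 ± 0.11 against 3.14 ± 0.05, a rise of at least 36.5-fold (adjusted p = 2.1e-09). LSMEM1 rose at least 38.4-fold, CEL, a lipase of pancreatic juice, at least 27.5-fold, LCT, the intestinal lactase, at least 17.8-fold, AGBL2 at least 16.0-fold and LRRN4CL at least 11.95-fold. GCNA, a germ cell protein, rose by 6.10 ± 0.27 and the growth factor gene FGF18 by 5.78 ± 0.44 on the log2 scale. The largest falls were in SYT1 (203999_at), a calcium sensor of vesicle fusion, from 9.50 ± 0.38 to 2.70 ± 0.54 (at least 45.3-fold, adjusted p = 1.5e-05), and in EXOC4 (224926_at), a subunit of the exocyst, at least 37.5-fold. PTPRG fell at least 28.7-fold, ARHGAP6 21.5-fold, GPHN 21.5-fold, PSD3 19.2-fold and DIAPH2 15.2-fold, and SCEL fell by 5.29 ± 1.02 (log2). In all, 5631 of 10972 genes were called, 3002 higher and 2629 lower, of which 1245 and 1123 changed at least 2-fold.

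Among the fixed lists, 20 of 33 mitotic genes fell and 1 rose with the high dose of Aa at 24 h (22 adjusted over the list alone), including the kinesin CENPE (-1.54 ± 0.11) and DLGAP5 (-1.73 ± 0.13). Camera, which tests a list against all other genes, gave adjusted p = 5.8e-05, and adjusted p = 0.553 with an estimated correlation. Targets of NRF2, the regulator of antioxidant genes, rose in 16 of 25 cases and fell in 1 (17 adjusted over the list alone), with OSGIN1 at least 2.64-fold and HMOX1, heme oxygenase, by 1.11 ± 0.22. The list had adjusted p = 0.0055, and adjusted p = 0.0630 with an estimated correlation. Of 20 cholesterol synthesis genes 13 fell and 0 rose (13 adjusted over the list alone), among them the sterol reductase TM7SF2 (-2.06 ± 0.30) and INSIG1 (-1.32 ± 0.18) (adjusted p = 0.0023, and adjusted p = 0.182 with an estimated correlation). Of 9 replication-dependent histone genes 7 rose, with H2AC6 by 2.40 ± 0.41 and H2BC12 by 1.48 ± 0.27 (8 adjusted over the list alone; adjusted p = 0.0155, and adjusted p = 0.553 with an estimated correlation). Such near-identical histone genes can share probe signal, so single members are uncertain. Interferon-stimulated genes rose in 12 of 26 cases and fell in 1 (13 adjusted over the list alone), with IFIT2 by 1.59 ± 0.22 and MX1 at least 1.72-fold (adjusted p = 0.0270, and adjusted p = 0.730 with an estimated correlation). This call was lost without control replicate 1 or 3 or high dose replicate 2 (adjusted p = 0.0555, 0.0513 and 0.0955).

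Other lists held changed members without a call for the list in this comparison. Of 28 p53 targets 10 rose and 5 fell (15 adjusted over the list alone), with CDKN1A, the cyclin-dependent kinase inhibitor p21, up by 1.57 ± 0.19 and GADD45A by 1.81 ± 0.20. The list's median was -0.02, its mean 0.12 and its adjusted p 0.737. MDM2, the ubiquitin ligase of p53, did not pass (0.24 ± 0.15, adjusted p = 0.196), nor did the proliferation marker MKI67 (-0.14 ± 0.14, adjusted p = 0.424; another MKI67 probe set was called the other way). The stress factors ATF3 (5.40 ± 0.40), STC2 (3.35 ± 0.25) and DDIT3 (1.39 ± 0.18) rose. Of the list, 15 of 29 ATF4 and amino acid stress genes rose while 4 fell (19 adjusted over the list alone; adjusted p = 0.0529, 0.0416 with the replicate block, 0.0393 floored and 0.0286 without high dose replicate 2, but adjusted p = 0.553 with an estimated correlation, and 0.643 with the block as well). E2F1 (1.52 ± 0.21), E2F2 (1.47 ± 0.14) and the exonuclease EXO1 (1.36 ± 0.18) rose, and ERCC1 fell by 1.32 ± 0.18, although another ERCC1 probe set was called the other way. AHRR (at least 2.15-fold) and ALDH1A3 (1.99 ± 0.37) of the aryl hydrocarbon receptor targets rose, as did the glycolytic ALDOC (at least 9.49-fold), the cytokine IL6 (2.83 ± 0.88; adjusted p = 0.0550 without control replicate 1) and NFKBIA (1.67 ± 0.12). The apoptosis gene PMAIP1 (1.76 ± 0.26), HBEGF (2.902 ± 0.358) and NQO1 (0.64 ± 0.16; adjusted p = 0.0775 with all 36 arrays in 1 fit) rose. HAVCR1, the injury marker KIM-1, fell by 1.08 ± 0.16, as did KRT20 (-2.99 ± 0.62, floored -2.65), SLC3A1 (-2.04 ± 0.49), BCL2 (-1.95 ± 0.47), CA12 (-3.49 ± 0.91), CDH1 (-1.54 ± 0.37) and CDH2 (-1.62 ± 0.23). With the replicate block the DNA replication list (13 of 31 higher, 4 lower), the aryl hydrocarbon receptor list (5 of 7 higher, 1 lower) and the kidney injury (8 of 22 lower, 2 higher) and proximal tubule lists (7 of 13 lower, 1 higher) were also called, each at adjusted p = 0.0418. None of these 4 held with an estimated correlation, at adjusted p = 0.730, 0.401, 0.401 and 0.730 without the block, and 0.643, 0.560, 0.560 and 0.560 with it, a combination chosen after seeing the data.

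**Figure D2:**
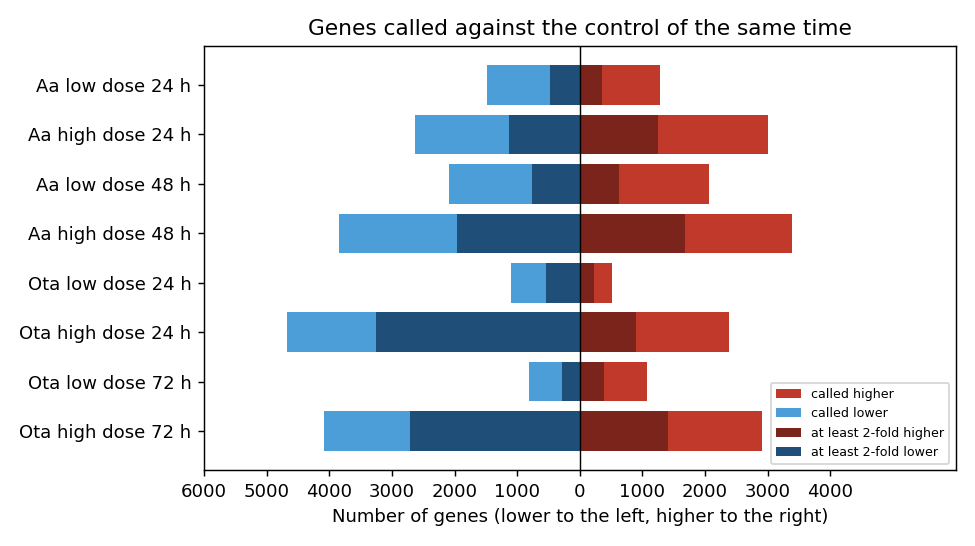
Number of genes called (limma, adjusted p under 0.05) higher (right) and lower (left) than the control of the same time, for each compound, dose and time; dark parts changed at least 2-fold. In both compounds the high dose called more genes than the low dose, with 7240 in Aa high dose at 48 h and 7058 in Ota high dose at 24 h.

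The low dose of Aa at 24 h raised GCNA by 4.96 ± 0.27, LCT at least 4.81-fold and OIT3 at least 6.00-fold. The interferon-induced IFI35 (-4.10 ± 0.24, floored -3.62) and TSPAN31 (-3.63 ± 0.43) fell, and NANOS1 fell at least 11.7-fold. Cholesterol synthesis genes fell in 10 of 20 cases with 0 rises (10 adjusted over the list alone; adjusted p = 4.1e-05, and adjusted p = 0.0821 with an estimated correlation). DNA replication genes rose in 13 of 31 cases with 0 falls (13 adjusted over the list alone; adjusted p = 0.00039, and adjusted p = 0.524 with an estimated correlation). Mitotic genes fell in 13 of 33 and rose in 1 (19 adjusted over the list alone; adjusted p = 0.0011, and adjusted p = 0.763 with an estimated correlation). The low dose called 2753 genes, 1277 higher and 1476 lower. With the replicate block the count was 4190, and the ER chaperone list (median -0.20) was also called (adjusted p = 0.0215). That list had adjusted p = 0.524 with an estimated correlation and no block, and 0.611 with both.

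At 48 h the high dose of Aa raised SHISA2 at least 87.0-fold, AOC3 at least 66.9-fold, LSMEM1 at least 53.02-fold, and CEL at least 36.3-fold. MYH3, a myosin of embryonic muscle, rose at least 30.5-fold, the kinase WNK4 at least 28.01-fold and the muscle glycogen phosphorylase PYGM at least 19.4-fold. ATF3 rose from 5.02 ± 0.59 to 11.9 ± 0.40, a change of 6.90 ± 0.40. EXOC4 fell at least 39.97-fold and the protein kinase PRKCB at least 30.6-fold. GPR160 (-6.73 ± 0.75, floored -5.30), SYT1 (-6.62 ± 0.88, floored -5.39), PTPRG (-6.13 ± 0.65, floored -5.40), ANK3 (-6.05 ± 1.14, floored -5.22), ARHGAP6 (-6.03 ± 0.56, floored -5.10) and GPHN (-5.95 ± 0.70, floored -4.81) fell on the log2 scale. All 9 tested histone genes rose, by a median of 3.14, with H2BC4 at least 11.8-fold and H3C2 at least 7.77-fold (9 adjusted over the list alone; adjusted p = 2.3e-05, and adjusted p = 0.477 with an estimated correlation). Altogether 7240 genes were called, 3393 higher and 3847 lower, of which 1680 and 1964 changed at least 2-fold.

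Of 27 immediate early genes 17 rose and 5 fell at 48 h (22 adjusted over the list alone), with FOSB at least 17.7-fold. Of 27 ribosome biogenesis genes 17 rose and 3 fell (20 adjusted over the list alone), with NOP2 up by 2.19 ± 0.14 and LYAR by 1.89 ± 0.21. Both lists had adjusted p = 0.0060; with an estimated correlation they had adjusted p = 0.477 and adjusted p = 0.710. The p53 targets were mixed again, 11 higher and 8 lower of 28 (19 adjusted over the list alone, adjusted p = 0.469). GADD45A rose by 3.05 ± 0.20 and CDKN1A by 2.02 ± 0.19, and MDM2 fell by 0.55 ± 0.15 (adjusted p = 0.0721 with all 36 arrays in 1 fit). The cytokines IL11 (at least 19.3-fold) and IL6 (4.94 ± 0.88, floored 4.31), the growth factor HBEGF (5.62 ± 0.36), and the transcription factor SNAI1 (at least 10.7-fold) rose. So did TAGLN (3.72 ± 0.40, floored 3.27), ANGPTL4 (at least 20.99-fold), ALDOC (at least 17.1-fold), PMAIP1 (3.13 ± 0.26), E2F1 (2.29 ± 0.21), MCM10 (2.26 ± 0.21) and EXO1 (2.23 ± 0.18). MKI67 rose by 1.20 ± 0.14 (another of its probe sets was called the other way), AURKB by 1.34 ± 0.20, DDIT3 by 1.12 ± 0.18, NQO1 by 0.72 ± 0.16 and OSGIN1 at least 3.95-fold. In the 48 h controls MKI67 was at 10.96 ± 0.28, and in those at 24 h at 11.66 ± 0.18. HMOX1 did not pass (-0.10 ± 0.22, adjusted p = 0.711). Of the proximal tubule genes 9 of 13 fell and 2 rose (11 adjusted over the list alone, adjusted p = 0.164), with the bicarbonate transporter SLC4A4 at -3.05 ± 0.39 and the amino acid transporter subunit SLC3A1 at -3.43 ± 0.49. TM7SF2 (-3.20 ± 0.30), INSIG1 (-2.42 ± 0.18), KRT20 (-4.90 ± 0.62, floored -4.64), BCL2 (-3.86 ± 0.47, floored -3.16), TIPARP (-2.98 ± 0.21), SLC7A11 (-1.95 ± 0.44), XBP1 (-1.33 ± 0.12) and HAVCR1 (-1.03 ± 0.16) fell.

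The low dose of Aa at 48 h raised CEL at least 8.54-fold, WNK4 at least 5.83-fold and GCNA by 4.72 ± 0.27, and lowered WWOX (-4.96 ± 0.68, floored -3.81), GPC6 (-4.86 ± 0.62, floored -4.44) and ANK2 (-4.25 ± 0.60, floored -3.55). Mitotic genes were higher in 28 of 33 cases with 0 lower (30 adjusted over the list alone; median 0.75, adjusted p = 4.0e-12, and adjusted p = 0.648 with an estimated correlation). DNA replication genes rose in 12 of 31 and fell in 4 (17 adjusted over the list alone; adjusted p = 0.0149, 0.0519 without low dose replicate 2, and adjusted p = 0.733 with an estimated correlation). Histones rose in 8 of 9 (8 adjusted over the list alone; adjusted p = 0.0012, and adjusted p = 0.648 with an estimated correlation). Immediate early genes rose in 14 of 27 and fell in 3 (19 adjusted over the list alone; adjusted p = 0.00995, and adjusted p = 0.648 with an estimated correlation). The low dose called 4158 genes, 2064 higher and 2094 lower. The mitotic and DNA replication lists fell in the controls from 24 h to 48 h, so their rises here are against a lower control level. For Aa no comparison with the 24 h controls was made.

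High and low doses of Aa were then compared directly. At 24 h the high dose gave higher PYGM (at least 7.89-fold), SLC25A34 (at least 10.7-fold) and PNLDC1 (at least 5.23-fold) than the low dose, and lower ARHGAP6 (at least 13.5-fold), PSD3 (at least 9.43-fold) and SYT1 (at least 8.95-fold). NRF2 targets were higher in 8 of 25 with 0 lower (9 adjusted over the list alone; adjusted p = 0.0132, and adjusted p = 0.104 with an estimated correlation). At 48 h IL11 (at least 19.3-fold), RND1 (at least 11.4-fold) and FOSB (4.85 ± 0.54, floored 3.76) were higher, and ANK3 (-4.35 ± 1.14, floored -3.52), LRBA (-4.10 ± 0.50) and ARHGAP24 (-4.09 ± 0.62, floored -3.41) lower. Mitotic genes were lower at the high dose than at the low dose in 27 of 33 cases at 48 h (27 adjusted over the list alone; adjusted p = 5.9e-09, and adjusted p = 0.519 with an estimated correlation). Mitotic genes were lower in 7 and higher in 0 at 24 h (7 adjusted over the list alone; adjusted p = 0.0015, and adjusted p = 0.667 with an estimated correlation). Interferon-stimulated genes were higher at 24 h in 11 of 26 (12 adjusted over the list alone, with the same adjusted p values). At 48 h histones, ribosome biogenesis genes and immediate early genes were also called higher, with medians of 1.93, 0.57 and 0.42 and adjusted p = 3.0e-06, 0.00085 and 0.0347 (each adjusted p = 0.519 with an estimated correlation). The comparisons called 2970 genes at 24 h (1878 higher, 1092 lower) and 5107 at 48 h (2298 higher, 2809 lower). At 24 h, shifting each array to the same median moved the split to 1373 higher and 1618 lower.

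The high dose effect of Aa changed between 24 h and 48 h in 2276 genes, 783 with a higher and 1493 with a lower change at 48 h. IL11 (5.19 ± 0.34, floored 4.27), FOSB (5.10 ± 0.76, floored 4.15) and SLN (4.82 ± 0.82) gained most, and BLNK (-3.57 ± 0.96, floored -2.85), the iron exporter gene SLC40A1 (-3.20 ± 0.54, floored -2.84) and TMEM37 (-3.13 ± 0.73) lost most. Histones gained in 8 of 9 cases (8 adjusted over the list alone; adjusted p = 2.3e-08, and adjusted p = 0.275 with an estimated correlation). Mitotic genes gained in 16 of 33 (18 adjusted over the list alone; adjusted p = 5.6e-09, and adjusted p = 0.300 with an estimated correlation). Heat shock (0.28), NF-kB (0.67), immediate early (0.54), ribosome biogenesis (0.44), TGF-beta and matrix (0.29) and proteasome lists (0.18) were also called with a gain, and metallothioneins (-0.73) with a loss, given as medians. With an estimated correlation their adjusted p lay between 0.300 and 0.612. The mitotic list fell in the controls over the same time. Across the 10972 genes the changes at 24 h and 48 h correlated with r = 0.857 and rho = 0.803 (genes are not independent replicates). At both times 2233 genes were called higher and 2213 lower, against 928 and 922 for independent lists. With the replicate block 4111 genes were called, and with arrays shifted to the same median 1055 were higher and 1068 lower.

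In the Aa controls, from 24 h to 48 h, BLNK rose by 3.64 ± 0.68 (floored 2.85), KISS1R at least 2.88-fold and PLA1A by 1.78 ± 0.28. The collagenase MMP1 (-3.08 ± 0.23), the thioredoxin inhibitor TXNIP (-2.91 ± 0.51) and SLN (-2.85 ± 0.58) fell. Mitotic genes fell in 8 of 33 cases with 0 rises (31 adjusted over the list alone; adjusted p = 1.4e-25, and adjusted p = 0.0803 with an estimated correlation). DNA replication genes fell in 5 of 31 (15 adjusted over the list alone; adjusted p = 1.9e-10, and adjusted p = 0.0803 with an estimated correlation). The DNA repair (-0.20), heat shock (-0.15), ribosome biogenesis (-0.16), TGF-beta and matrix (-0.11) and proteasome lists (-0.24) were called lower, and the ATF4 (0.25), cholesterol (0.07) and ribosomal protein lists (0.05) higher, given as medians, and none of them held with an estimated correlation. In this comparison 142 genes were called, 62 higher and 80 lower. The replicate block called 1599. It was set within a time and did not pair the 24 h with the 48 h controls, so that count is not a paired result. The 6 control arrays by themselves called 0, and leaving out 1 array gave between 17 (without 24 h replicate 3) and 550 genes (without 48 h replicate 3). On the 6 arrays alone BLNK, KISS1R, PLA1A, MMP1, TXNIP and SLN all lost their calls, at adjusted p from 0.0534 to 0.194. Calls were also lost without 24 h replicate 1 (BLNK, SLN), 2 (SLN, TXNIP) or 3 (BLNK, PLA1A, SLN, TXNIP), and without 48 h replicate 1 or 2 (all of these), at adjusted p from 0.0579 to 0.144.

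Ota was examined in the same way. At 24 h its high dose raised FGF18 (231382_at) from 3.14 ± 0.11 to 11.6 ± 0.21, at least 196-fold (adjusted p = 1.9e-09). AVIL, an actin-binding protein of the villin family, rose at least 63.6-fold, the histone gene H2BC4 (236193_at) at least 44.6-fold, and the Wnt antagonist FRZB at least 41.5-fold. MSH4, a meiotic mismatch repair homolog, rose at least 39.8-fold, AOC3 at least 28.2-fold, the paraoxonase PON1 at least 13.5-fold and NPR3 at least 12.4-fold. TMEM37 (1554485_s_at) fell at least 70.3-fold, PCDH7 at least 69.3-fold (another of its probe sets was called the other way), and NBPF20 at least 50.9-fold. PET117 fell at least 31.3-fold, MED21, a Mediator subunit, at least 31.2-fold and AREL1 at least 26.4-fold. TMEM139 (-6.90 ± 0.48, floored -5.73) and the CTP synthase CTPS1 (-6.35 ± 0.49, floored -5.78) fell on the log2 scale. The comparison called 7058 of 11029 genes, 2379 higher and 4679 lower, of which 901 and 3258 changed at least 2-fold. The split changed with the scaling and with the filter. The median change of the tested genes was -0.26 as deposited, -0.05 after quantile normalization (3287 higher, 3999 lower) and 0.38 with arrays shifted to the same median (5193 higher, 2943 lower). Without a filter, over 19775 genes as deposited, the median was 0.03, with 5376 higher and 4699 lower, of which 978 and 3255 changed at least 2-fold.

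Relative to that median, histones stood out with 11 of 12 members higher with Ota high dose at 24 h and a median of 2.83 (floored 2.60; 11 adjusted over the list alone; adjusted p = 1.4e-08, and adjusted p = 0.0798 with an estimated correlation). H2AC6 rose by 5.28 ± 0.28. DNA replication genes fell in 21 of 31 cases and rose in 2 (23 adjusted over the list alone; median -1.21, floored -1.11, adjusted p = 0.0086, and adjusted p = 0.618 with an estimated correlation). The clamp loader genes RFC4 (-3.74 ± 0.21) and RFC3 (-3.58 ± 0.38) fell most. ER chaperones were higher in 9 of 21 and lower in 2 (11 adjusted over the list alone; adjusted p = 0.0134, and adjusted p = 0.749 with an estimated correlation; 0.0605 with shifted arrays). DNAJC3 rose by 1.13 ± 0.29. XBP1 fell (-1.798 ± 0.244), although another XBP1 probe set was called the other way. Ribosomal proteins were higher in 8 of 32 with 0 lower (6 adjusted over the list alone; adjusted p = 0.0017, and adjusted p = 0.618 with an estimated correlation). So were 11 of 33 oxidative phosphorylation subunits, with 3 lower (14 adjusted over the list alone; adjusted p = 0.0086, and adjusted p = 0.618 with an estimated correlation). RPL38 rose by 1.12 ± 0.21, RPL22 by 0.90 ± 0.10 and NDUFB6 by 0.60 ± 0.10.

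Uncalled lists held large falls in Ota high dose at 24 h. The p53 targets POLH (at least 9.66-fold) and ZMAT3 (-3.04 ± 0.35) fell, MDM2 fell by 2.49 ± 0.33 and CDKN1A rose by 0.65 ± 0.20. Of all, 16 of 28 p53 targets fell and 5 rose (22 adjusted over the list alone, adjusted p = 0.365). MKI67 (-3.33 ± 0.21), CCNB1 (-3.64 ± 0.25) and AURKB (-3.57 ± 0.19) fell, with 19 of 33 mitotic genes lower and 3 higher (22 adjusted over the list alone, adjusted p = 0.0859, and 0.0168 without high dose replicate 3). The repair factors XPA (-4.74 ± 0.29, floored -4.03) and CHEK1 (-4.60 ± 0.26), the apoptosis regulator BCL2L2 (at least 5.94-fold), JUND (-4.36 ± 0.33), DDIT4 (-4.13 ± 0.14), and the RNA sensor RIGI (at least 14.3-fold) fell, as did VCAM1 (-3.84 ± 0.29), NOB1 (-3.94 ± 0.33), the renal transcription factor PAX8 (-2.51 ± 0.35) and NSDHL (-2.71 ± 0.24). RRP12 fell at least 7.80-fold, against another of its probe sets. STC2 (4.49 ± 0.38), ATF3 (4.01 ± 0.40, floored 3.80), MMP1 (3.59 ± 0.63), RSAD2 (2.88 ± 0.35), TNFAIP3 (2.62 ± 0.33), AHRR (at least 3.11-fold) and ALDOC (at least 4.002-fold) rose. HAVCR1 (-0.43 ± 0.35, adjusted p = 0.301; 0.0352 on its own 6 arrays) and NQO1 (0.17 ± 0.37, adjusted p = 0.711) did not pass. DDIT3 (-1.21 ± 0.46, adjusted p = 0.0291) and HMOX1 (-1.04 ± 0.38, adjusted p = 0.0244) passed narrowly. DDIT3 lost the call in 8 alternatives, at adjusted p from 0.0536 to 0.223, among them both scalings and the fits without control replicate 1 (0.0632) or 2 (0.0723) or high dose replicate 1 (0.0663) or 2 (0.182). HMOX1 lost it in 5, at adjusted p from 0.0745 to 0.300, among them both scalings and the fits without control replicate 1 (0.0745) or high dose replicate 2 (0.132).

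**Figure D3:**
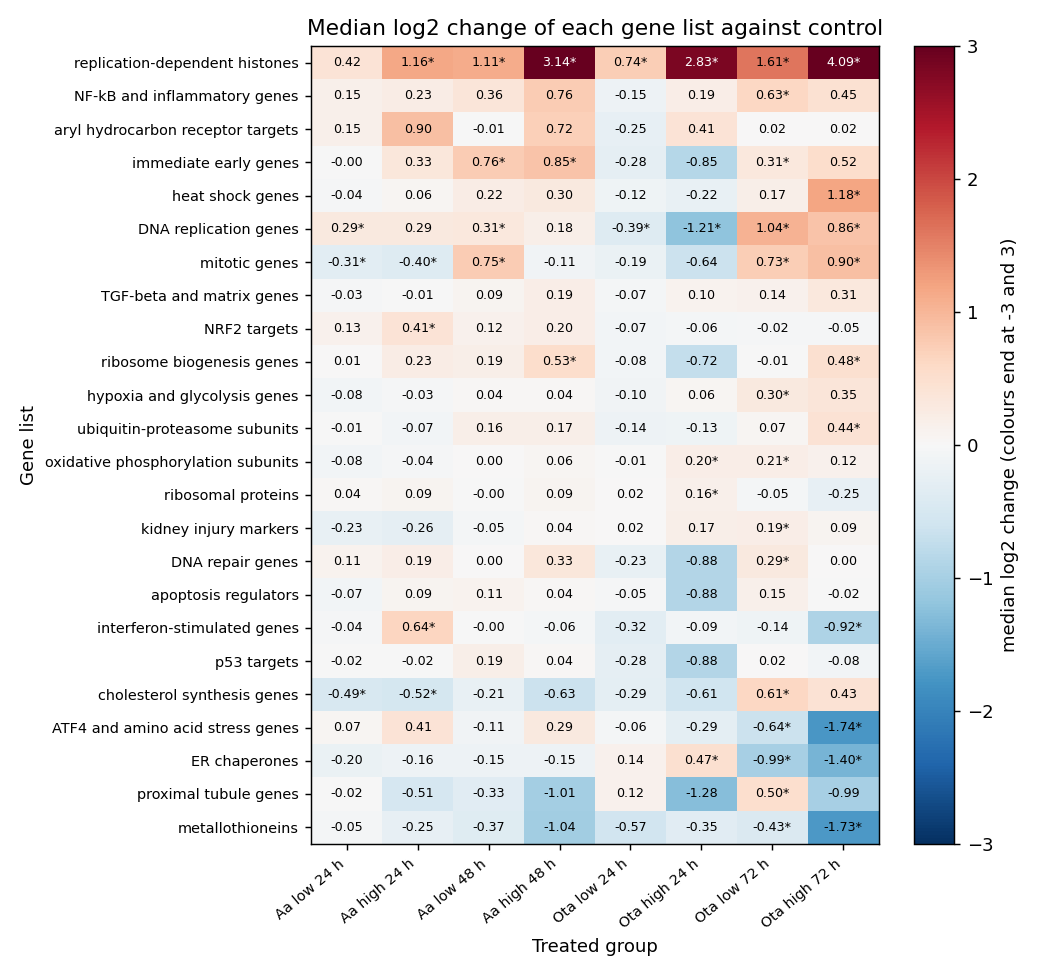
Median log2 change of each tested gene list (rows) in each treated group against its control (columns); an asterisk marks lists called by camera at the preset correlation. Replication-dependent histones have the highest medians, 4.09 in Ota high dose at 72 h (3.77 floored) and 3.14 in Aa high dose at 48 h.

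The low dose of Ota at 24 h raised the histone genes H2AC6 by 5.40 ± 0.28 and H2BC4 at least 8.90-fold, and the dehydrogenase DHRS2 at least 4.45-fold. IFI35 fell at least 9.10-fold, and TLCD1 (-3.53 ± 0.39, floored -3.39) and the centriole gene SPICE1 (-3.29 ± 0.42, floored -2.64) fell too. Histones were higher in 6 of 12 cases (6 adjusted over the list alone; adjusted p = 8.7e-08, and adjusted p = 0.109 with an estimated correlation). DNA replication genes were lower in 5 of 31 with 0 higher (9 adjusted over the list alone; adjusted p = 0.00064, and adjusted p = 0.881 with an estimated correlation). It called 1619 genes, 514 higher and 1105 lower. Without low dose replicate 2 it called 942, and with shifted arrays 947 were higher and 752 lower.

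At 72 h the high dose of Ota raised H2BC4 at least 86.4-fold, AOC3 at least 45.4-fold, the linker histone H1-2 at least 37.6-fold, the neuropeptide gene GAL at least 34.4-fold, SPMIP1 at least 23.2-fold, MSH4 at least 17.6-fold and ZNF513 at least 16.07-fold. GAL had fallen in the controls from 24 h to 72 h (floored -3.80), so its rise is against a lower control level. PLAUR, the urokinase receptor, rose from 4.74 ± 0.20 to 10.6 ± 0.11. METTL23 (225808_at) fell at least 116-fold (adjusted p = 8.8e-14), RUFY1 at least 34.1-fold, the ligand NRG1 at least 30.5-fold and HOGA1 at least 21.3-fold. GPR160 (-6.38 ± 0.33, floored -5.77), TMEM37 (-6.08 ± 0.45, floored -5.77), KDELR3 (-5.91 ± 0.79, floored -5.55) and WDR13 (-5.86 ± 0.31, floored -5.71) fell on the log2 scale. All 12 histone genes rose, by a median of 4.09 (floored 3.77; 12 adjusted over the list alone; adjusted p = 5.5e-10, and adjusted p = 0.0468 with an estimated correlation). In all 6989 genes were called, 2903 higher and 4086 lower, of which 1408 and 2718 changed at least 2-fold. The median change of the tested genes was -0.12, and with arrays shifted to the same median it was 0.20, with 4370 higher and 3083 lower.

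Stress gene lists were lower with Ota high dose than in the control at 72 h. Of 30 ATF4 and amino acid stress genes 26 fell and 1 rose (27 adjusted over the list alone; adjusted p = 1.2e-06, and adjusted p = 0.449 with an estimated correlation). CBS fell at least 34.6-fold, and ALDH1L2 (-5.09 ± 0.54, floored -4.70) and DDIT3 (-4.17 ± 0.46) fell on the log2 scale. Of 21 ER chaperones 14 fell and 0 rose (15 adjusted over the list alone; adjusted p = 0.0016, and adjusted p = 0.593 with an estimated correlation), among them SDF2L1 (-4.27 ± 0.27) and HYOU1 (-3.09 ± 0.25). These lists had risen in the controls between 24 h and 72 h, and against the 24 h controls, a comparison chosen after seeing the data, their medians were 0.07 and 0.99. Mitotic genes were higher in 21 of 33 and lower in 5 (26 adjusted over the list alone; adjusted p = 0.00022, and adjusted p = 0.596 with an estimated correlation), with TTK at 1.84 ± 0.18 and KIF2C at 1.70 ± 0.19. Replication genes were higher in 19 of 31 and lower in 5 (24 adjusted over the list alone; adjusted p = 0.00022, and adjusted p = 0.449 with an estimated correlation), with MCM10 at 4.03 ± 0.15 and RFC4 at -4.54 ± 0.21. Against the 24 h controls these medians were -0.96 and -0.58.

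Heat shock genes rose in 12 of 16 cases and fell in 2 with Ota high dose at 72 h (14 adjusted over the list alone; adjusted p = 0.00068, and adjusted p = 0.449 with an estimated correlation). The co-chaperone gene BAG3 rose by 2.18 ± 0.21 and HSPH1 by 1.96 ± 0.23. Proteasome subunits and related ubiquitin genes rose in 15 of 27 and fell in 2 (17 adjusted over the list alone; adjusted p = 0.00018, and adjusted p = 0.449 with an estimated correlation). Against the 24 h controls this call was lost (adjusted p = 0.0533). PSMD1 rose by 1.82 ± 0.11 and PSMD4 fell by 2.00 ± 0.20. Ribosome biogenesis genes rose in 14 of 27 and fell in 2 (16 adjusted over the list alone; adjusted p = 0.0073, and adjusted p = 0.596 with an estimated correlation). Metallothioneins fell in 7 of 9 and rose in 1 (8 adjusted over the list alone; adjusted p = 0.0210, and adjusted p = 0.555 with an estimated correlation), with MT1F at -2.56 ± 0.16. Interferon-stimulated genes fell in 16 of 25 and rose in 4 (20 adjusted over the list alone; adjusted p = 0.0418, and adjusted p = 0.449 with an estimated correlation), with IFI44L at -3.32 ± 0.26 and IRF9 at -2.92 ± 0.30. The interferon call was lost without control replicate 3 (adjusted p = 0.0617) or high dose replicate 1 (0.0513). The p53 targets TP53I3 (at least 18.5-fold) and CCNG1 (-2.30 ± 0.13) fell while CDKN1A rose by 2.05 ± 0.20. Of 28 targets 7 rose and 11 fell (18 adjusted over the list alone, adjusted p = 0.753), and MDM2 did not pass (-0.53 ± 0.33, adjusted p = 0.173; 0.0396 on its own 6 arrays). XPA (at least 30.5-fold), TM7SF2 (-4.92 ± 0.52, floored -4.08), LOX (-4.20 ± 0.33), SLC7A11 (-3.50 ± 0.28), NQO1 (-3.50 ± 0.37), SLC4A4 (-3.43 ± 0.20), SLC3A1 (-3.29 ± 0.23), VCAM1 (-3.45 ± 0.29) and CCL2 (-3.19 ± 0.48) fell. MMP1 (at least 24.4-fold), IL6 (at least 15.3-fold), the helicase BLM (3.56 ± 0.23, floored 3.46), HBEGF (3.42 ± 0.34), KLF10 (2.88 ± 0.25), ADM (2.73 ± 0.24) and MKI67 (0.77 ± 0.21) rose. The MKI67 level was 9.70 ± 0.22 with the high dose, 8.93 ± 0.32 in the 72 h controls and 11.25 ± 0.13 in the 24 h controls. PHLDA1 rose by 2.86 ± 0.29 on its own probe set, but 3 others were called the other way. HAVCR1 (-0.46 ± 0.35, adjusted p = 0.265; -0.98 and 0.00520 without high dose replicate 3) and HMOX1 (0.20 ± 0.38, adjusted p = 0.658) did not pass.

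**Figure D4:**
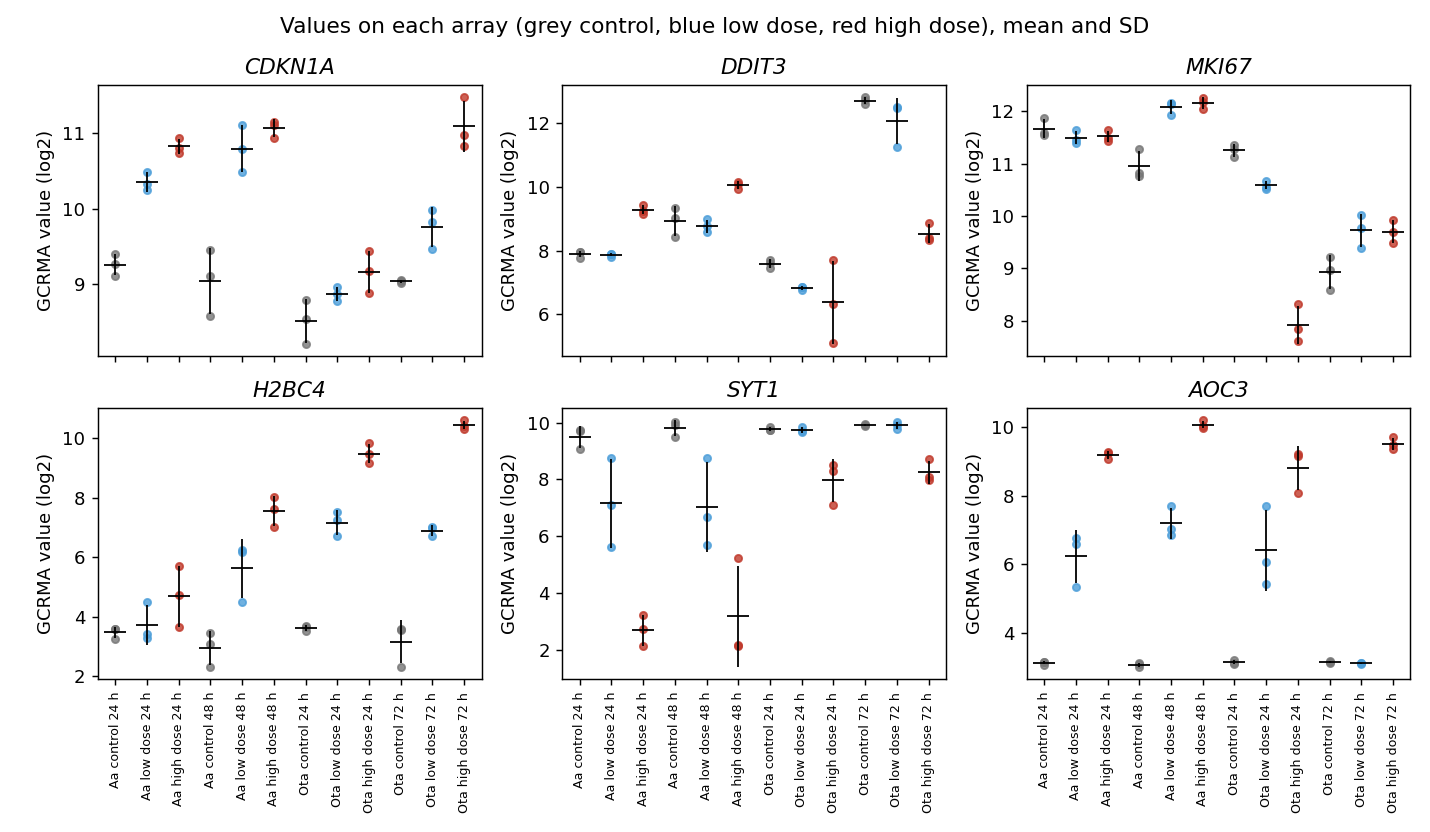
GCRMA log2 values of CDKN1A, DDIT3, MKI67, H2BC4, SYT1 and AOC3 on each of the 36 arrays by group (points), with the group mean (dash) and SD (bar). DDIT3 reached 12.7 in the Ota controls at 72 h against 7.59 at 24 h, and SYT1 fell to 2.70 in Aa high dose at 24 h.

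The low dose of Ota at 72 h raised DHRS2 at least 12.5-fold, H2BC4 at least 7.44-fold and H1-2 at least 7.40-fold, and lowered LAMP3 (-3.13 ± 0.53, floored -2.04), ALDH1L2 (-3.12 ± 0.54) and JMJD4 (at least 3.47-fold). DNA replication genes rose in 25 of 31 and fell in 1 (28 adjusted over the list alone; adjusted p = 2.0e-19, and adjusted p = 0.0336 with an estimated correlation). Histones rose in 8 of 12 (8 adjusted over the list alone; adjusted p = 1.3e-09, and adjusted p = 0.0336 with an estimated correlation). ER chaperones fell in 17 of 21 (20 adjusted over the list alone; adjusted p = 1.9e-14, and adjusted p = 0.106 with an estimated correlation). ATF4 and amino acid stress genes fell in 16 of 30 (18 adjusted over the list alone; adjusted p = 1.5e-09, and adjusted p = 0.106 with an estimated correlation). Mitotic genes rose in 19 of 33 (26 adjusted over the list alone; adjusted p = 1.5e-11, and adjusted p = 0.198 with an estimated correlation). Cholesterol synthesis genes rose in 9 of 20 (10 adjusted over the list alone; adjusted p = 2.8e-05, and adjusted p = 0.209 with an estimated correlation). DNA repair (0.29), NF-kB (0.63, floored 0.37), immediate early (0.31), hypoxia (0.30), proximal tubule (0.50), kidney injury (0.19) and oxidative phosphorylation genes (0.21) were also called higher, and metallothioneins (-0.43) lower, given as medians. With an estimated correlation their adjusted p lay between 0.156 and 0.532. Of these, the NF-kB call was lost without control replicate 2 (adjusted p = 0.0914) or low dose replicate 3 (0.231), and the kidney injury call without low dose replicate 2 (0.0637) or 3 (0.0544). The hypoxia and metallothionein calls were lost without control replicate 2 (0.0851 and 0.0579) and without low dose replicate 2 (0.0977 and 0.0738) or 3 (0.0737 and 0.0736). Against the 24 h controls the ER chaperone and ATF4 medians turned to 1.20 and 1.25, and those of replication, mitotic, DNA repair, hypoxia and oxidative phosphorylation genes to -0.41, -1.11, -0.25, -0.14 and -0.10. The kidney injury list lost its call against them (adjusted p = 0.380). HAVCR1, which the naming rule gave only for high doses, was at 11.55 ± 0.04 with this low dose. Its level was 9.92 ± 0.26 in the 72 h controls and 10.77 ± 0.05 in the 24 h controls. Its other low dose and control means were 10.77 and 10.77 (Ota, 24 h), 11.05 and 11.28 (Aa, 24 h), and 10.98 and 11.25 (Aa, 48 h). The comparison called 1883 genes, 1080 higher and 803 lower, and 1170 without control replicate 3 or 1184 without low dose replicate 1. Fitted on its own 6 arrays it called 3479.

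Between the doses of Ota, the high dose at 24 h gave higher FGF18 (8.14 ± 0.52, floored 7.58), MSH4 (at least 39.8-fold) and FRZB (6.21 ± 0.59, floored 5.24), and lower TMEM37 (at least 46.7-fold), CARD10 (-6.17 ± 0.51, floored -5.38) and AREL1 (at least 19.1-fold). At 72 h it gave higher AOC3 (at least 45.4-fold), MSH4 (at least 17.6-fold) and GAL (5.82 ± 0.41, floored 5.07), and lower TMEM37 (-6.21 ± 0.45, floored -5.90), RNASEH2A (-5.89 ± 0.39, floored -5.64) and GPR160 (-5.86 ± 0.33, floored -5.25). Histones were higher at the high dose in 10 of 12 cases at 24 h (10 adjusted over the list alone; adjusted p = 5.9e-06, and adjusted p = 0.245 with an estimated correlation). All 12 were higher at 72 h (12 adjusted over the list alone; adjusted p = 2.5e-09, and adjusted p = 0.0594 with an estimated correlation). At 24 h ER chaperones, metallothioneins, oxidative phosphorylation subunits and ribosomal proteins were also called higher, with medians from 0.12 to 0.32. At 72 h heat shock (0.82), ribosome biogenesis (0.44) and proteasome genes (0.72) were called higher, and ATF4 (-1.20), metallothionein (-1.30) and proximal tubule genes (-1.60) lower, given as medians. With an estimated correlation none of these held, with adjusted p between 0.438 and 0.649. The comparisons called 6413 genes at 24 h (2144 higher, 4269 lower) and 6437 at 72 h (2394 higher, 4043 lower). With shifted arrays the splits were 4743 and 2716 at 24 h, and 4088 and 2836 at 72 h; quantile normalization gave 3100 and 3584 at 24 h.

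The high dose effect of Ota differed between 72 h and 24 h in 5939 genes, 3642 with a higher and 2297 with a lower change at 72 h. The DNA polymerase gene POLQ (7.37 ± 0.34, floored 6.45), the nuclear pore gene NUP85 (6.24 ± 0.79, floored 5.99) and CTPS1 (6.18 ± 0.70, floored 5.60) gained most, and ALDH1L2 (-6.14 ± 0.77, floored -5.55), GPR160 (-5.49 ± 0.47, floored -4.88) and FOXP2 (-5.36 ± 0.40, floored -5.16) lost most. Mitotic genes gained in 30 of 33 cases (30 adjusted over the list alone; adjusted p = 5.0e-08, and adjusted p = 0.309 with an estimated correlation). ER chaperones lost in 16 of 21 (17 adjusted over the list alone; adjusted p = 8.3e-08, and adjusted p = 0.277 with an estimated correlation). Replication (1.94), repair (1.24), histone (1.29, floored 1.06), heat shock (1.56), immediate early (1.00), ribosome biogenesis (1.52) and proteasome genes (1.00) also gained, and ATF4 (-1.65), metallothionein (-1.41), interferon-stimulated (-0.42, floored -0.31) and ribosomal protein genes (-0.46) lost, given as medians. With an estimated correlation their adjusted p lay between 0.219 and 0.359. In the controls over the same time the ER chaperone and ATF4 lists rose and the mitotic and replication lists fell. Those changes enter these gains and losses. Against the 24 h controls, a comparison chosen after seeing the data, the high dose medians at 72 h were 0.99 (ER chaperones), 0.07 (ATF4), -0.96 (mitotic) and -0.58 (replication). Across 11029 genes the changes at the times correlated with r = 0.522 and rho = 0.489. With shifted arrays 2768 genes had a higher and 3249 a lower change.

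In the Ota controls, from 24 h to 72 h, ATF3 rose by 5.58 ± 0.40 (floored 5.37), INHBE by 5.56 ± 0.36 and DDIT3, the stress factor CHOP, by 5.10 ± 0.46. TXNIP fell by 6.02 ± 0.44, GAL at least 13.9-fold and SCN3A at least 7.40-fold. ATF4 and amino acid stress genes rose in 28 of 30 cases (29 adjusted over the list alone; adjusted p = 3.4e-23, and adjusted p = 0.0191 with an estimated correlation). ER chaperones rose in 21 of 21 (21 adjusted over the list alone; adjusted p = 1.7e-21, and adjusted p = 0.0431 with an estimated correlation). Mitotic genes fell in 33 of 33 (33 adjusted over the list alone; adjusted p = 2.7e-27, and adjusted p = 0.0561 with an estimated correlation). DNA replication genes fell in 27 of 31 (27 adjusted over the list alone; adjusted p = 1.2e-20, and adjusted p = 0.0209 with an estimated correlation). DNA repair (-0.46), metallothionein (-0.88), hypoxia (-0.21), proteasome (-0.34) and oxidative phosphorylation genes (-0.37) were also called lower and ribosomal proteins (0.17) higher, given as medians, and none of these held with an estimated correlation. In all 3282 genes were called, 1540 higher and 1742 lower.

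The compounds were compared at 24 h through the difference of their high dose effects, which are not matched in concentration. ARID1B (6.80 ± 0.40, floored 6.30), PRKCB (6.29 ± 0.74, floored 4.70) and CELF2 (5.92 ± 0.55, floored 4.97) had a higher change with Ota than with Aa, and CARD10 (-6.89 ± 0.55, floored -6.10), TIMM23B (-6.81 ± 0.29, floored -5.39) and AREL1 (-6.68 ± 0.22, floored -5.00) a lower one. Histones had a higher change with Ota in 10 of 12 cases and a lower one in 1 (11 adjusted over the list alone; adjusted p = 2.0e-05, and adjusted p = 0.242 with an estimated correlation). DNA replication genes had a lower one in 23 of 31 (24 adjusted over the list alone; adjusted p = 0.00030, and adjusted p = 0.434 with an estimated correlation). Ribosome biogenesis (-1.14) and DNA repair genes (-0.85) were also called lower, and ER chaperones (0.46), kidney injury markers (0.49, floored 0.31), TGF-beta and matrix genes (0.47), oxidative phosphorylation subunits (0.28) and ribosomal proteins (0.08) higher, given as medians. With an estimated correlation their adjusted p lay between 0.267 and 0.704. Altogether 6775 of 11405 genes differed, 2129 higher and 4646 lower. The median of the tested genes was -0.33 as deposited, -0.12 after quantile normalization (2789 higher, 3933 lower) and 0.42 with shifted arrays (4974 higher, 2780 lower). Without a filter it was 0.05, with 5510 higher and 4658 lower.

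The effects of the compounds overlapped weakly at the high dose at 24 h. Across the 10649 genes tested in both, r was 0.236 (jackknife SE 0.0296) and rho 0.184. Genes called higher with both numbered 790 against 587 for independent lists, and genes called lower with both 1469 against 1140; 1057 were higher with Aa and lower with Ota, against 1224, and 326 were the reverse, against 547. AOC3 and FGF18 were among the largest rises with each compound at 24 h. At the low dose at 24 h r was 0.558, with 244 genes higher (57.0 for independent lists) and 584 lower (150 for independent lists) with both compounds, IFI35 among them. The high dose effects of Aa at 48 h and Ota at 72 h, times that differ, had r = 0.385.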

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

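The tests of the stress gene lists against the 24 h controls, the values floored at 4 and the splits that keep or exchange pairs were chosen only after the result was seen. The rule for array normalization with Ota at 24 h was set down beforehand and later changed. The 3 results on how a high dose effect changed with time or compound are differences between effects, tested as interactions. The splits, the asymmetry with Ota at 24 h and the stress lists at 72 h are other patterns.

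Between 24 h and 48 h the effect of the high dose of Aa differed in 2276 genes. Among those named, IL11 (5.19, floored 4.27), FOSB (5.10, floored 4.15) and SLN (4.82) gained on the log2 scale, and BLNK (-3.57, floored -2.85), SLC40A1 (-3.20, floored -2.84) and TMEM37 (-3.13) lost. Of 100 relabelings of the arrays within the contrast, the real one included, 7 gave at least 2276 genes, the highest 7690, so these relabelings did not exclude chance for the count. Swapping most labels at 1 time only turns the difference of the effects toward their sum. Of the 6 others that reached the count, 5 lay on the side of the sum, and 1, with 2291 genes, on that of the difference. Replicate numbers paired the Aa cultures. Of the 32 relabelings that part every pair, 6, the real one included, gave as many genes, and 5 did with the replicate block (real count 4111, highest other 8468). The highest of these swapped all labels at 1 time, which tests the sum; the highest of the rest called 5431 and 5651 genes. When the differences within the pairs were exchanged between the times, which leaves the shared effect in place, the real split called 3559 genes and the highest of the 9 others called 0. There are 10 such splits, too few for a share under 0.05.

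Between 24 h and 72 h the effect of the high dose of Ota differed in 5939 genes. The controls themselves changed in 3282 genes over that time, and those changes enter the difference. POLQ (7.37, floored 6.45), NUP85 (6.24, floored 5.99) and CTPS1 (6.18, floored 5.60) gained, and ALDH1L2 (-6.14, floored -5.55), GPR160 (-5.49, floored -4.88) and FOXP2 (-5.36, floored -5.16) lost. Of 100 relabelings, 1, the real one, gave as many, and the highest other gave 4499. These ignored that the numbers paired the cultures at 24 h. They also mix treated and control arrays within a time, which breaks up the effect the times share. They therefore cannot exclude chance for a difference between the effects. Of 80 relabelings that part every pair at 24 h, 2 gave as many: the real one, and the one that swaps all labels at 1 time and so tests the sum of the effects (8005 genes). The highest of the rest gave 4599. Between the compounds at 24 h, the high dose effect differed in 6775 genes. ARID1B (6.80, floored 6.30), PRKCB (6.29, floored 4.70) and CELF2 (5.92, floored 4.97) had a higher change with Ota than with Aa. CARD10 (-6.89, floored -6.10), TIMM23B (-6.81, floored -5.39) and AREL1 (-6.68, floored -5.00) had a lower one. These are differences of the 2 effects, and a fall with Aa gives a higher value as a rise with Ota does. Among 100 relabelings drawn without regard to pairs, 1, the real one, gave as many, with 5719 as the highest other. These too break up the effect the compounds share, so they cannot exclude chance for a difference. The numbers paired these cultures, and of the 32 relabelings that part every pair 2 gave as many, the real one and, with 7420 genes, the one that swaps all labels of 1 compound and so tests the sum of the effects. The highest of the rest gave 5529. With 2 of 32 the share was not under 0.05. With differences within the pairs exchanged between the compounds, the real split called 6599 genes and the highest of the 9 others 0, again among 10 splits.

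Splits of 3 arrays against 3 number 10, too few for a share under 0.05, and in each of these comparisons 1 split, the real one, gave as many genes. In the comparisons with paired numbers, 4 of the 10 part every pair, and the other 3 of these called at most 2 genes. For Aa the real count and the highest other were 5631 and 0 (high dose, 24 h), 2753 and 1 (low dose, 24 h), 7240 and 0 (high dose, 48 h), 4158 and 0 (low dose, 48 h), 2970 and 0 (high against low dose, 24 h), 5107 and 2 (high against low dose, 48 h) and 142 and 3 (controls over time). For Ota they were 7058 and 1 (high dose, 24 h), 1619 and 0 (low dose, 24 h), 6989 and 0 (high dose, 72 h), 1883 and 3 (low dose, 72 h), 6413 and 5 (high against low dose, 24 h), 6437 and 0 (high against low dose, 72 h) and 3282 and 1 (controls over time).

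With the high dose of Ota at 24 h, 3258 genes fell and 901 rose at least 2-fold. No single array carried this, since the lowest ratio of falls to rises with 1 array left out was 3.02 (without high dose replicate 2). Loss of short-lived zinc finger transcripts is argued against: the median change of 342 ZNF genes (-0.31) lay at percentile 77.0 of 10000 lists of like level. Array normalization remains a candidate explanation for part or all of it. The ratio of falls to rises was lower after quantile normalization, at 1.98 (2679 falls and 1350 rises). The rule set down beforehand counted a ratio of at most 1.5 after either scaling for array normalization. After shifting each array to the same median the ratio was 0.794, which met it. The shift adds 1 constant to all genes of an array, so its ratio was left out, a change to that rule. The ZNF genes were picked by symbol, without half-lives, so a loss of other short-lived transcripts was not tested. A lower amount of RNA per cell could not be measured on normalized arrays, and no other biological explanation was tested.

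With the high dose of Ota at 72 h, ATF4 and amino acid stress genes (median -1.74) and ER chaperones (-1.40) were lower than in the controls of that time. The controls themselves had risen from 24 h to 72 h, with medians of 1.81 and 2.25. Against the 24 h controls the high dose medians were 0.0727 and 0.99, so the lower values may come from the rise in the controls and not from a fall below the starting level. Whether the compound prevented that rise or the treated cultures used up the medium more slowly was not tested. The fall of TXNIP in the controls over the same time (-6.02) does not decide between these.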

How the results depend on the processing

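The fit with the 24 h Ota controls in place of the 72 h controls, values at or under 4 set to 4, and the replicate block together with an estimated correlation were chosen after seeing the data. Of 342 pairs of named gene and comparison, 342 kept direction and side of the threshold with the replicate block, 342 with trend and robust settings, 340 with quantile normalization, 338 with shifted arrays, 339 without a filter, 341 with values at or under 4 set to 4 and 331 on only the arrays compared. Leaving out 1 array kept 2126 gene results, weakened 33 and strengthened 1. For gene lists it kept 1123, weakened 16 and strengthened 13. Testing every probe set by itself raised the counts because more features were tested, for Aa to 11487 (high dose, 24 h), 5734 (low, 24 h), 14623 (high, 48 h), 7932 (low, 48 h), 5558 and 9845 (high against low, 24 h and 48 h) and 3925 (change of the high dose effect), for Ota to 14902 (high, 24 h), 4311 (low, 24 h), 14353 (high, 72 h), 3997 (low, 72 h), 13057 and 12928 (high against low, 24 h and 72 h), 11397 (change of the high dose effect) and 6098 (controls over time), and for Ota against Aa to 13887. Without a filter the last count was 10168. The replicate numbers paired the cultures in the Aa comparisons. The replicate block called 4190 genes for the low dose of Aa at 24 h and 4111 for the change of its high dose effect, with 10 lists for its high dose at 24 h. For its controls over time the block called 1599, without pairing controls of different times. The cause of these changes was not tested. For Ota at 72 h the numbers did not pair (lowest r -0.0566). For the Aa controls over time, trend and robust settings called 243 and the 6 arrays alone called 0 (4 residual degrees of freedom, 1877 at an unadjusted p under 0.05 in the fit of 18). For the low dose of Ota at 72 h the 6 arrays called 3479. Replicates in its 2 groups had median absolute differences of 0.134 to 0.171 (log2), against 0.264 to 0.512 in Ota high dose at 24 h. The fit of 18 gives all these groups 1 shared spread. Ota high dose against control at 24 h called 5774 on its own 6 arrays and 7058 in the fit of 18. The cause of these changes was not tested. With an estimated correlation the lists called were 0 for both doses of Aa at 24 h and 48 h, 0 for both doses of Ota at 24 h, 1 for its high dose at 72 h and 2 for its low dose at 72 h, because correlated members carry less evidence. With the replicate block as well they were 0 in each of these comparisons but the low dose of Ota at 72 h, with 1. With 1 array left out, the gene counts ran from 17 (without 24 h replicate 3) to 550 (without 48 h replicate 3) for the Aa controls over time, from 942 (without low dose replicate 2) to 1336 for the low dose of Ota at 24 h and from 1170 (without control replicate 3) to 1531 for its low dose at 72 h, and the lists called for the high dose of Ota at 24 h from 5 to 8 (without high dose replicate 3); the cause was not tested. HSPA4L was called higher in the high dose of Aa at 24 h. As the mean of its probe sets, which were called in opposite directions, it reversed to -0.11 and did not pass (adjusted p = 0.620). Against the 24 h controls, which differ from the 72 h ones by the measured change of the controls, the medians for the high dose of Ota at 72 h reversed to 0.0727 (ATF4 genes), 0.99 (ER chaperones), -0.58 (replication) and -0.96 (mitotic), and for its low dose to 1.25 (ATF4 genes), 1.20 (ER chaperones), -0.25 (DNA repair), -0.41 (replication), -1.11 (mitotic), -0.14 (hypoxia) and -0.10 (oxidative phosphorylation). Levels at or under a log2 value of 4 limit the folds of genes silent in 1 group to lower bounds. With such values set to 4, gene counts stayed within 1.5 times, 160 of the 342 named changes moved by over 0.1, and 1 call was lost (ALDH1A3, high dose of Ota at 72 h, 0.30, adjusted p = 0.256).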

Other observations

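The list of very long genes used in this part was written after the genes named in the report were seen, but its tests were set down before its own result was seen. Only the values floored at 4 and the test of RNA degradation as part of the fall were chosen after the results were seen.

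Many of the largest falls with Aa were in genes known for great length, such as EXOC4, PTPRG, GPHN, WWOX and ANK2. A list of 60 very long genes was therefore written from general knowledge, and the genes already named were left out of it. With the high dose of Aa, 39 of 43 tested members fell at 24 h and 0 rose (median -2.45), and 42 fell at 48 h and 0 rose (median -3.28). With values at or under 4 set to 4, 36 fell at 24 h (median -2.42) and 40 at 48 h (median -2.899). AGAP1 fell by 5.26 on the log2 scale at 24 h (floored -3.99), FARS2 by 4.96 (floored -4.11), SMYD3 by 4.72 and LPP by 3.82. The low dose gave 15 falls and 1 rise at 24 h (median -0.79, floored -0.65) and 31 falls at 48 h (median -1.59, floored -1.11), and the controls 0 calls over time. For the low dose the camera p against all genes was 0.181 and 0.0700 with an estimated correlation, so its calls at the preset correlation (1.1e-06 and 9.2e-12) did not hold.

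With the high dose of Ota the list was mixed at 24 h, with 14 of 45 members lower and 8 higher (median -0.12), and fell at 72 h in 29, with 4 rises (median -0.71). The change at 24 h was higher with Ota than with Aa in 31 members and lower in 0. Genes with symbols starting ZNF went the other way with Aa: 163 of 350 rose and 23 fell at 24 h (median 0.39), and 150 rose and 64 fell at 48 h (median 0.25).

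A candidate explanation is that the length of a gene sets how far it falls with Aa, as reduced transcription through long genes would give. The list's median lay at percentile 0 of 10000 lists of like level at both times. Camera against all genes gave an unadjusted p of 0.0280 at 24 h and 0.0433 at 48 h with an estimated correlation. Unlike those of the fixed lists, the camera p values of this list were not adjusted for other tests. RNA degradation as the whole cause is argued against. The high dose of Ota at 72 h had the widest gap between the 3' and 5' actin sets. It left these genes 2.41 ± 0.26 (SE, 43 genes) higher than Aa at 48 h did. That SE is over genes on the same arrays, which are not independent replicates, and leaves out the spread between cultures. As a part of the fall RNA degradation stays open, since the control sets differed. With the high dose of Aa the actin gap was 1.01 against 0.79 in the controls at 24 h and 1.25 against 0.86 at 48 h, higher in each of the 3 replicate pairs at both times. The list's median also lay below that of lists of like level with Ota at 72 h (-0.71 against -0.10, percentile 0.27), where the gap was 1.88 against 1.29. That fall had camera p = 0.0011 at the preset correlation, and did not hold at p = 0.0577 with an estimated one. Against the low dose of Ota at 72 h, 30 of 45 members were lower and 1 higher (camera p = 0.0418, estimated correlation). Against its high dose effect at 24 h, 25 had a lower change and 4 a higher one (camera p = 0.0200, estimated correlation). With Ota at 24 h the median lay at percentile 75.7, and the gap was 1.16 against 1.08. The gap of the GAPDH control sets moved little, to -0.04 from -0.09 (Aa, 24 h), -0.01 from -0.05 (Aa, 48 h) and -0.01 from -0.08 (Ota, 72 h), with SDs up to 0.07, and was lower than in the control in replicate 3 of Aa at 48 h. An effect of Ota on long genes would give the same values. Dim probe sets are argued against as well, since the 21 brighter members had a median of -1.95, at percentile 0, and the same with the floor. Gene lengths were not used here, so a trend over all genes was not tested, and the idea remains a hypothesis found and tested on the same data.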
